A study of Caenorhabditis elegans with 4 samples.

How the data were processed

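Chromatin immunoprecipitation followed by sequencing (ChIP-seq) with an affinity-purified rabbit polyclonal antibody raised against HIM-5 was carried out on extracts of young adult Caenorhabditis elegans hermaphrodites with a germ line, carrying the fem-2(b245) mutation and kept at 20 °C. There were 4 samples: 2 ChIP replicates and 2 input DNA samples, grouped by their titles. Per the labels' protocols, worms were frozen and ground, and the material was cross-linked with EGS followed by formaldehyde and sonicated, and single-end Illumina libraries were made with size selection on beads. Reads were aligned with BWA, per the submitters' processing notes, which also name the ce10 build, and the file headers give the corresponding WormBase release, WS220. The version of the aligner, the settings of the aligner and the peak caller, the filters on reads, and whether and how the input libraries were used in calling are not given in the sources used here.

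The deposited values were 3 lists of peaks, each peak with a chromosome, a start and an end in WS220 (1-based) and a score. The authors called the 2 replicate lists with a program given in the files as MACS and the series-level list with MACS v2. The score deposited for each peak is the authors' own value, on a scale that is not given in the sources used here. In the replicate lists it started at 50.02, stood at exactly 3100 for 25 peaks of replicate 1 and 20 of replicate 2, and exceeded that value for 1 peak in each, while in the series list it ran from 1.31 to 214.4. Scores were therefore used only within a list, to rank, filter or compare its peaks. Scores of different lists, where printed together, are not on a known common scale. It is not stated on which reads the series list was called. The peak coordinates, deposited as whole base positions, were used as given. Read counts and library sizes are unknown for all samples, so the depth behind a peak is unknown, and a peak missing from a list was treated as not called rather than unbound. The input samples were not analysed here, and a level of background measured in them is therefore not given. All intervals on counts and shares cover counting error only, and they treat peaks as independent, which neighbouring peaks are not.

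Before the data were examined, the comparisons, tests, named sites and most alternatives were fixed. Peaks on the 6 nuclear chromosomes were used, and mitochondrial peaks were kept apart. The length of each chromosome was taken as the span to the last peak end in any list, because a sequence of the WS220 build was not used here. Peak density was the number of peak midpoints per Mb in blocks of 1 Mb (a last block under 500 kb joined the one before it). The X chromosome, and then each chromosome in turn, was set against the others by a 2-sided permutation test of block labels (100000 permutations), with Benjamini-Hochberg adjustment over the 6 chromosomes. A bootstrap over blocks (10000 draws) gave 95% intervals of density ratios. The share of midpoints in the central 33.3% of the chromosomes (the middle-third share) was tested, 2-sided, against 10000 circular rotations of each chromosome's peaks, which keep their clustering. Overlap between the replicate lists meant at least 1 bp in common and was tested, 1-sided, against 10000 rotations of replicate 2. Scores of series peaks found in both replicate lists were compared with those of the other series peaks by a 2-sided permutation test of the medians (100000 permutations). Intervals of shares are exact Clopper-Pearson intervals and those of densities exact Poisson intervals, both at 95%. The threshold was a p-value of 0.05. These p-values measure spread along the genome or, for the scores, between single peaks, and not between worms. The labels do not say whether the 2 ChIP replicates came from separate cultures.

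Named sites were the 15 series peaks with the highest score that overlapped a peak in both replicate lists, and the 5 highest such peaks on X. Gene names were planned only for a reference of the same build. The gene table at hand is of another assembly, WBcel235, and coordinates of different builds were not mixed. Promoter shares, gene lists, noncoding RNA genes, GC content and the search for a pairing-centre motif on X were therefore not run. Alternatives covered each replicate list alone, the 50% of peaks with the higher score, series peaks in both replicate lists, merging of peaks less than 10 kb apart, blocks of 500 kb and 2 Mb, base pairs covered, the middle 50% of the chromosomes, an overlap of at least 50% of both peaks, midpoints within 200 bp, and uniform placement. Leaving out runs of neighbouring peaks, and leaving out peaks within 500 bp of the left chromosome ends, was added after seeing the data. The tests were checked on simulated lists. Simulated peaks were placed independently of each other, without the clustering of the real lists. These checks therefore do not show how the tests behave on clustered peaks. With 2000 simulated peaks, the X test passed the threshold in 40 of 40 lists at a true density ratio of 0.65 and in 0 of 40 at a ratio of 1.0. The test of chromosome centres passed in 40 of 40 at a true share of 42% and in 2 of 40 with no excess, and with 900 peaks per list the overlap test passed in 40 of 40 at 30% shared peaks and in 1 of 40 with none shared. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.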

Results

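HIM-5 is a C. elegans protein known for its part in forming meiotic double-strand breaks on the X chromosome, and fem-2 is a gene that promotes male fate, including sperm production, in the worm. The deposited series-level list held 2191 peaks on the nuclear chromosomes and 2 on mitochondrial DNA. The list of ChIP replicate 1 held 903 nuclear peaks and that of replicate 2 held 1014, a mean of 958.5 ± 78.5 (SD, n = 2), with 1 mitochondrial peak in each. Peaks covered 1148 kb, or 1.14% of the nuclear span, in the series list, 630 kb (0.628%) in replicate 1 and 734 kb (0.733%) in replicate 2. The median nuclear peak was 294 bp wide in the series list, 328 bp in replicate 1 and 404 bp in replicate 2. The widest nuclear peak in each list lay near the right end of the span of chromosome I, from 15060237 to 15071350 in the series list. Read depth is unknown for all samples.

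The first comparison asked how far the ChIP replicates marked the same sites. Of the 903 peaks of replicate 1, 540 overlapped a peak of replicate 2 (59.8%, exact 95% interval 56.5% to 63.02%), and 505 of the 1014 peaks of replicate 2 overlapped a peak of replicate 1 (49.8%, 46.7% to 52.9%). Rotating replicate 2 along the chromosomes gave a mean of 11.3 overlapped replicate 1 peaks and at most 101 (1-sided permutation p = 1e-04, the smallest that 10000 rotations can give). This test sets the overlap against random placement only. Background common to both libraries could also raise it, and no input profile was compared. Where an overlap had to span at least 50% of both peaks, the share of replicate 1 peaks was 36.5%. In base pairs, the lists shared 51.5% of their joint coverage. Wide sites were shared most: 67 of 70 replicate 1 peaks of 2 kb or more (95.7%) and 76 of 77 such replicate 2 peaks (98.7%) overlapped the other list, against 56.8% and 45.8% of the narrower peaks. An overlap of 1 bp sufficed here, which wide peaks meet more easily. The split at 2 kb was not among the planned comparisons. Shared peaks of replicate 1 had a median score of 226 and those found in replicate 1 alone 76.04. In replicate 2 these medians were 199.8 and 85.95.

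The series list took in most replicate peaks and many more sites. It overlapped 791 of the 903 replicate 1 peaks (87.6%) and 919 of the 1014 replicate 2 peaks (90.6%). Of its own 2191 peaks, 491 overlapped both replicate lists (22.4%, exact 95% interval 20.7% to 24.2%), 243 only replicate 1, 388 only replicate 2, and 1069 neither (48.8%, 46.7% to 50.9%). The list was thus neither the union nor the intersection of the replicate lists. Its peaks in neither replicate list had a median score of 4.33 and a median width of 216 bp. The series list was called with MACS v2 and the replicate lists with MACS, at unknown settings. Effects of the program and of the reads on the extra peaks cannot be told apart. Series peaks in both replicate lists had a median score of 14.7 (quartiles 9.06 and 24.8), and the other 1700 series peaks one of 4.87 (quartiles 3.64 and 6.80). This difference of 9.82 passed the threshold (2-sided permutation p = 1e-05, the smallest that 100000 permutations can give). Single peaks were shuffled as if independent, which neighbouring peaks are not. The reads behind the series list are not stated, but the series holds no ChIP samples beyond these 2 replicates. A higher series score for peaks called in both replicates would follow from shared reads. The comparison is therefore not independent evidence. Among the 100 series peaks with the highest score, 84 were in both replicate lists, against 70 of the 1191 from rank 1001 down (5.88%). The share in both lists was 25.7% on X (20.5% to 31.3%) and between 18.3% on chromosome III and 26.1% on chromosome V among the autosomes. Where an overlap had to span at least 50% of both peaks, series peaks in both replicate lists fell to 9.72%, and the difference of median scores was 15.3.

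The 15 series peaks with the highest score among those in both replicate lists lay on 5 of the 6 chromosomes. The peak with the highest score of the series list, 214.4, spanned 6847467 to 6849866 on chromosome I and met 1 peak in replicate 1 and 4 in replicate 2. Next came 1503427 to 1505113 on X with a score of 210.0, 11913023 to 11919270 on chromosome IV with 193, 16929246 to 16939920 on X with 173.2, and 13907378 to 13910535 on chromosome V with 172.8. The replicate peaks at these 5 sites had a highest score of 3100 in both lists. Chromosome I held 2 more of the 15 named sites, at 7656546 to 7660881 (score 172) and 7489538 to 7493445 (131). Chromosome V also held 2 more, at 9546710 to 9547424 (166) and 2730102 to 2731159 (122.2). On chromosome IV, 3 sites between 11323942 and 11401572 had scores from 148.5 to 149.7. On chromosome II, 3 sites lay between 13819658 and 13825609, with scores of 118.9, 120.3 and 133. Replicate scores at these 3 chromosome II sites were 209 to 373 in replicate 1 and 1499 to 1667 in replicate 2. No site of the 15 lay on chromosome III. After its first 2, the next X sites stood at rank 53 (6252037 to 6254135, score 50.4), rank 62 (8718187 to 8719027, 41.5) and rank 63 (13349265 to 13351072, 40.7). The genes at these sites are not named here.

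Because HIM-5 is known for its part in X chromosome recombination, the X was set against the autosomes. The X carried fewer called peaks than the autosomes in the series list: 269 of 2191 peaks (12.3%, exact 95% interval 10.9% to 13.7%), although it made up 17.7% of the span. Its 18 blocks held 15.4 ± 7.72 peaks per Mb (SD over blocks) and the 82 autosomal blocks 23.4 ± 11.4, a ratio of 0.655 (bootstrap 95% interval 0.502 to 0.822, 2-sided permutation p = 0.006). Replicate 2 gave 12.4% of peaks on X and a ratio of 0.655 (0.505 to 0.833, permutation p = 0.012). Replicate 1 also gave a ratio below 1, 0.778, with 14.4% of peaks on X, but its interval of 0.545 to 1.06 included 1 and the call was lost (permutation p = 0.2). The call was also lost among the series peaks in both replicate lists, where X held 14.1% of peaks and the ratio was 0.752 (0.519 to 1.04, permutation p = 0.23). Among the 50% of series peaks with the higher score the ratio was 0.755 (0.578 to 0.963) and the permutation p was 0.06. In base pairs covered, X held 13.5% of the series total, a ratio of 0.730 (permutation p = 0.038), with 8.77 kb covered per Mb of X and 11.02 to 12.67 kb per Mb of the autosomes. Replicate 2 likewise covered less of X, 5.62 kb per Mb, than of any autosome (6.13 to 8.78 kb). In replicate 1, X had 6.02 kb per Mb, more than chromosome II (5.10 kb) and chromosome IV (5.82 kb). The median score of series peaks was 6.12 on X and 5.20 to 6.08 on the autosomes. In no list or setting run did X hold more peaks per Mb than the autosomes.

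**Figure D1:**
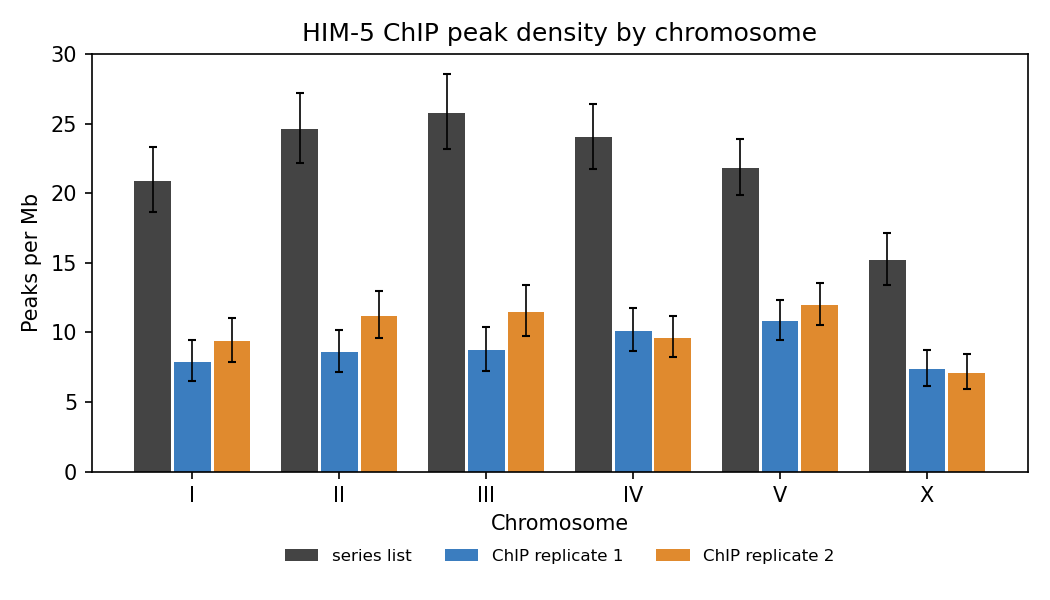
Peaks per Mb (vertical axis) on each chromosome (horizontal axis) in the series list and the 2 ChIP replicate lists, with exact Poisson 95% intervals as error bars, which cover counting error only. X has the shortest bar in each list, 15.2 peaks per Mb in the series list, 7.34 in replicate 1 and 7.11 in replicate 2.

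Among single chromosomes, X was the only one to pass the threshold against the others in the series list (adjusted permutation p = 0.036). The autosomes ran from 20.9 peaks per Mb on chromosome I to 25.8 on chromosome III, and their adjusted permutation p-values ran from 0.35 to 0.93. Over the replicates, X held 7.22 ± 0.160 peaks per Mb (SD, n = 2), chromosome I 8.63 ± 1.03, chromosome IV 9.86 ± 0.364, chromosome II 9.88 ± 1.85, chromosome III 10.1 ± 1.95 and chromosome V 11.4 ± 0.811. In each replicate list taken alone no chromosome passed after adjustment, with adjusted permutation p-values for X of 0.59 in replicate 1 and 0.07 in replicate 2. At an unadjusted p of 0.05 none passed in replicate 1 and X alone passed in replicate 2. Chromosome III passed as denser than the others in the series list only where peaks less than 10 kb apart were merged (ratio 1.44, adjusted permutation p = 3e-04) or runs of neighbouring peaks were left out (1.38, adjusted permutation p = 0.018). The densest block of the series list was the last of chromosome III, from 13 Mb on, at 65.1 peaks per Mb, with 30.6 in replicate 1 and 14.04 in replicate 2. It held a run of 17 neighbouring series peaks from 13074990 to 13085664 and another of 17 from 13584942 to 13598745. None of these run peaks was in both replicate lists, and none scored above 10.48.

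The chromosome centres, taken as the central 33.3% of each span, held more peaks in the series list than their share of length. There, 900 of 2191 midpoints lay in the centres (41.1%, exact 95% interval 39.01% to 43.17%), against a rotation mean of 33.3% (2-sided permutation p = 0.0067). In replicate 2 the share was 42.1% (permutation p = 0.0083). In replicate 1 it was 36.4% and did not pass (permutation p = 0.38). On the autosomes together the series share was 41.1% (permutation p = 0.015), a call lost in replicate 1 (38.2%, permutation p = 0.21) and in series peaks of both replicate lists (42.4%, permutation p = 0.093). X alone did not pass, although its share of 40.9% was close to that of the autosomes (permutation p = 0.12). The X share was 39.7% in replicate 2 but 26.2% in replicate 1, below the rotation mean, and neither passed (permutation p = 0.13 and 0.64). The series share on X also dropped to 33.3% with neighbouring peaks merged and 33.8% with runs left out. In the higher-scoring 50% it was 35.9%. The 69 X peaks in both replicate lists gave 46.4% (permutation p = 0.015, unadjusted), the only X setting to pass. In the middle 50% of the chromosomes X held 52.0% of its peaks (permutation p = 0.83) and the autosomes 62.5% (permutation p = 1e-04). The difference between X and the autosomes was not tested. No single chromosome passed after adjustment in any list. The lowest adjusted permutation p was 0.26, in replicate 2. In the series list the shares ran from 32.7% on chromosome I to 45.5% on chromosome II (unadjusted permutation p = 0.19). The simulated lists did not check this test on single chromosomes, so a missing call there does not show an even spread.

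**Figure D2:**
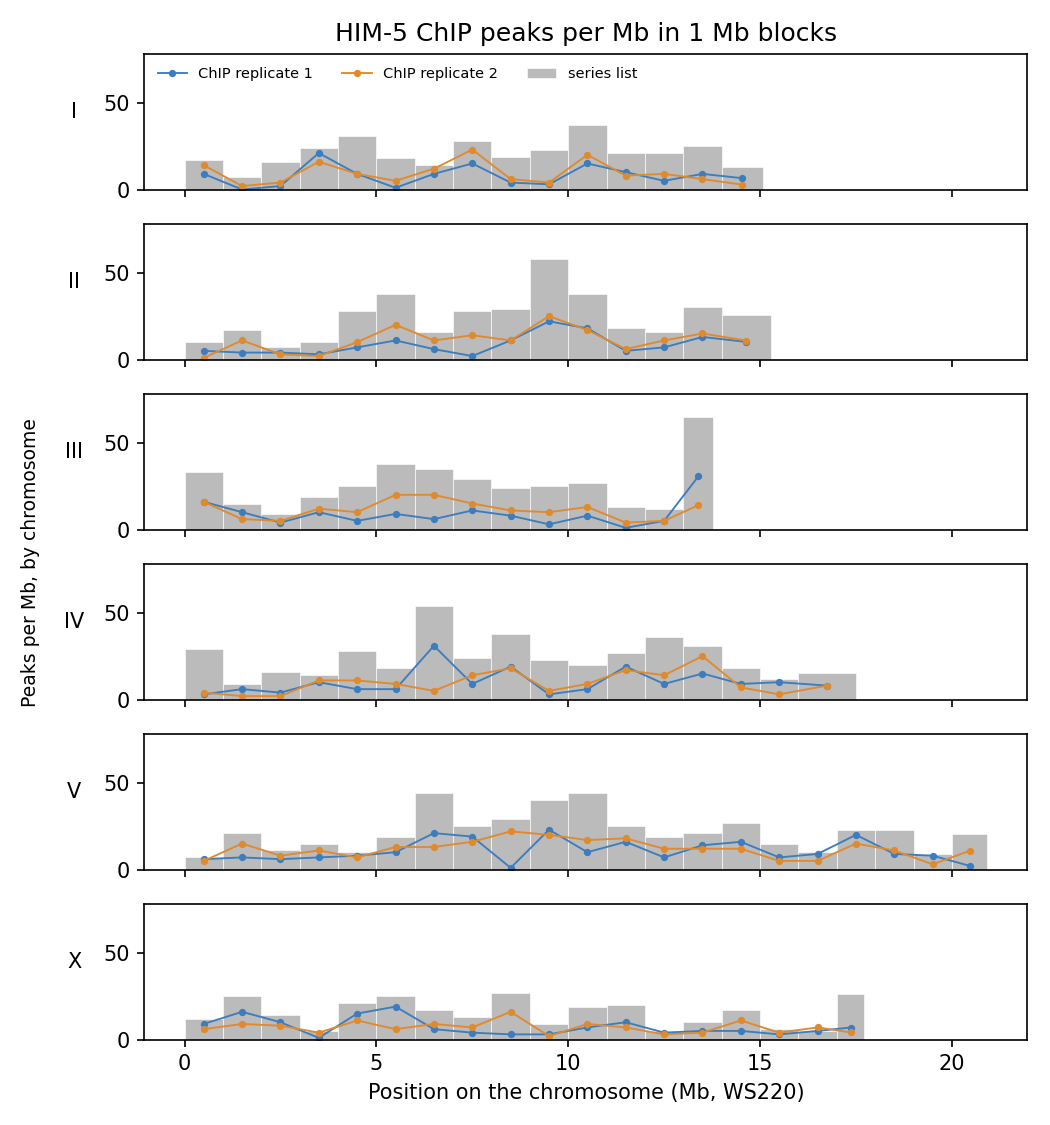
Peaks per Mb (vertical axis) in blocks of 1 Mb along each chromosome (horizontal axis, Mb in WS220), with bars for the series list and lines for the 2 ChIP replicates. Bars are low along most of X. They reach 65.1 in the last block of chromosome III, which holds runs of 17 neighbouring peaks with none in both replicate lists. On chromosome IV the block from 6 to 7 Mb has 31 peaks per Mb in replicate 1 and 5 in replicate 2.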

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

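The mitochondrial peaks lay outside the comparisons above and were looked at after the data were seen. A single peak covered nearly the whole mitochondrial span of 13824 bp in each list: 96.4% in the series list (positions 1 to 13327), 97.3% in replicate 1 (2 to 13447) and 96.9% in replicate 2 (1 to 13391). Its score lay above 96.8% of the series peaks, 92.7% of the replicate 1 peaks and 97.9% of the replicate 2 peaks, where it was 3100. The series list had a second mitochondrial peak from 13658 to 13824.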

How the results depend on the processing

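The overlap between the replicate lists stayed far above random placement in all 6 alternatives, at 36.5% (at least 50% of both peaks) to 61.3%. The score difference of series peaks in both replicate lists kept its direction and call, at 15.3 against 9.82, where an overlap had to span at least 50% of both peaks. As the lists may share reads, that score difference is not independent evidence. The lower X share kept its direction in all 10 alternatives but lost its call in 3: with replicate 1 alone (14.4%; the replicate lists alone gave 12.4% to 14.4%), in the 50% of peaks with the higher score (13.7%) and in series peaks of both replicate lists (14.1%). In these 3 the density ratio was 0.752 to 0.778, against 0.655 in the series list, and the cause was not tested. The replicate lists also differ from the series list in the calling program and the number of peaks. The number of chromosomes that passed was 1 in the series list. It was 0 in each replicate list, in the higher-scoring 50%, in series peaks of both replicate lists and for base pairs covered, and 2 (III and X) with neighbouring peaks merged or runs left out. The middle-third share kept its call except with replicate 1 alone (36.4%, with 42.1% for replicate 2 alone). On the autosomes alone it also lost its call with replicate 1 alone (38.2%) and in series peaks of both replicate lists (42.4%). Series peaks in both replicate lists moved to 9.72% when an overlap had to span at least 50% of both peaks. Density ratios of autosomes, none of which had passed, changed side of 1 as follows, the cause not being tested. With each replicate list alone, chromosome II gave 0.936 to 1.13, III 1.00 to 1.16, IV 0.945 to 1.16 and V 1.24 to 1.25. In series peaks of both replicate lists, I gave 1.04, II 0.924, III 0.958 and V 1.21. For base pairs covered, I gave 1.00, IV 0.965 and V 1.12. Chromosome I gave 1.204 with peaks merged and 1.01 without runs, and V gave 1.10 in the higher-scoring 50% and 1.01 with 2 Mb blocks. The X middle-third share, which had not passed, was 26.2% with replicate 1 alone, 39.7% with replicate 2 alone and 33.3% with peaks merged. It was 33.8% without runs and 35.9% in the higher-scoring 50%. In series peaks of both replicate lists it was 46.4% and passed (permutation p = 0.015). The settings leaving out runs and leaving out chromosome-end peaks, were chosen after seeing the data. Leaving out a replicate could not be applied to the overlap and score comparisons, which need both. No paired analysis was possible because the input samples were not analysed here, so no test compares ChIP with input samples of the same number. Promoter, gene list, noncoding RNA, GC and motif results were not run. Unknown read depth limits what a missing peak can show.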

Other observations

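The tests on chromosome ends and on runs of peaks were chosen only after the results were seen, and those on the X density were planned before. Many sites formed runs of neighbouring peaks with gaps under 2 kb. In the series list 415 peaks (18.9%) lay in 46 runs of 6 or more, and 24.3% of these were in both replicate lists, against 21.96% of the peaks outside runs. The longest by number held 24 peaks from 6711265 to 6730927 on chromosome IV, with no score above 8.05 and only 2 peaks in both replicate lists. Another held 22 peaks from 9808537 to 9824244 on chromosome II, none in both lists. By contrast, all 11 peaks of a run from 9428600 to 9434786 on chromosome V, and 10 of 11 from 10361059 to 10368977 on X, were in both lists.

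Each nuclear chromosome had a peak at its left end, within 500 bp of position 1, in all 3 lists. These peaks started at position 1 in the series list and no later than position 6 in the replicates. The right ends were not tested, because the span of each chromosome was itself taken from the last peak. Scores ran from 3.34 on chromosome IV to 47.5 on chromosome I in the series list, from 410 to 1535 in replicate 1 and from 460 to 1995 in replicate 2.

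The first pattern weighed is the lower peak density on X. Dense autosomal runs do not account for it, since merging peaks less than 10 kb apart left a ratio of 0.614 (bootstrap interval 0.499 to 0.745). By its bootstrap interval, a ratio of 0.755 in the higher-scoring 50% (0.578 to 0.963) goes against the lower-scoring 50% as the whole cause. The ratio was 0.655 (0.502 to 0.822) in the full list. That restriction also ended the permutation call, at p = 0.06, with a ratio nearer 1. Among series peaks in both replicate lists the ratio was 0.752, and its interval of 0.519 to 1.04 included 1 (permutation p = 0.23). Whether weak peaks near the calling threshold are the whole cause is therefore not settled. X held 131 of the 1191 series peaks from rank 1001 down, 13.8% at ranks 501 to 1000 and 15.2% at ranks 101 to 500. Of the 100 highest-scoring peaks it held 8. These differences between ranks were not tested, and a part played by weak peaks stays open. No biological explanation was tested, since the design holds no group that differs in X chromatin.

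The second pattern is the left-end peak on all 6 chromosomes. Chance placement of peaks is argued against, since rotations of the series list gave a mean of 0.122 and at most 3 such ends (permutation p = 1e-04, the smallest that 10000 rotations can give). Excess reads from repeats collapsed in the reference, in any library, could give the same peaks, and the 6 ends found in both replicate lists cannot be told apart from that, because no input profile was compared. No biological explanation was tested.

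The third pattern is runs of 6 or more peaks in a replicate list with no overlap at all in the other: 3 of 17 runs in replicate 1 and 4 of 13 in replicate 2. An example is 14 peaks within 8521 bp on X, from 5045452 to 5053972, all in replicate 1. Independent loss of single peaks, as called, is argued against. Shuffling which peaks were shared within 4 classes of score gave a mean of 0.237 such runs and at most 3, against 7. The permutation p was 1e-04, the smallest that 10000 shuffles can give. The shuffles treat each peak as a separate unit, but a run may be 1 enriched region split in calling. In replicate 1 these runs of 10, 8 and 14 peaks met 12, 9 and 10 series peaks. In replicate 2 the runs of 6, 6, 6 and 7 peaks met 4, 2, 6 and 5. The shuffles therefore do not show that separate sites were lost together. Weak peaks near the calling threshold stay open for these runs as a set. Run medians were 62.3 to 80.0 in replicate 1, against a list median of 121.6. In replicate 2 they were 93.6 to 559.9, against a list median of 117.9, with the highest from 1140865 to 1146067 on chromosome II. The median score of such a run lay at or above the median of its list in 0 of 3 runs of replicate 1 and 3 of 4 of replicate 2, and below the 25th percentile of the list in 1 and 0 of them. No biological explanation was tested.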
